A study of Homo sapiens with 8 samples.

How the data were processed

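Bulk RNA sequencing measured polyadenylated RNA in 8 libraries of a mixture of cardiomyocytes (90%) and fibroblasts (10%), both derived from WTC11, an established line of human induced pluripotent stem cells (hiPSCs). The titles placed 3 libraries at day 0, 2 at day 30 of conventional 2D culture and 3 at day 30 in 3D tissues grown in a melt-electrowritten scaffold, and gave the replicate numbers. RNA was extracted with Trizol and libraries were made with a stranded Illumina mRNA ligation kit, per the labels' protocols. The labels did not say whether replicates were separate differentiations or cultures, so every p-value measures the spread between these samples, which may be technical. The library name of 2D replicate 1 lists cardiomyocytes alone, whereas its title gives the mixture, and the title was followed.

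The deposited table held whole-number counts per Ensembl gene, not normalised, for all 8 libraries. Per the submitters' processing notes, the tools named were bcl2fastq 2.2.0, STAR 2.7.0d, featureCounts and DESeq2, with the GRCh38 build. The annotation release, the strand setting and the treatment of multi-mapped reads were not given in the sources used here. Counts of overlapping genes on opposite strands, of paralogs and of pseudogenes are therefore uncertain. Of 65 genes given by the naming rule below and checked for this, 33 overlap a gene on the other strand in GENCODE 29. BNC1, VTN and CDKN2B are covered over their whole span by genes on the other strand, so their counts are uncertain.

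Of 60666 identifiers, 60437 matched a table of gene symbols and 229 did not. Coordinates are 1-based and come from GENCODE 29 on GRCh38. Library totals ran from 21864393 to 42064789 counts. Where a group held no read of a gene, fold changes were bounded with a floor of 3 counts over the group, and this floor covers counting error only, because reads without molecular identifiers are not independent molecules. A chi-square comparison of counts separated every pair of replicates far beyond sampling noise, so none was taken as a second sequencing of the same library. It does not show whether replicates came from separate cultures.

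Genes were kept by the filterByExpr rule of edgeR 4.0.16 with group as the factor (minimum count 10), which left 19355 of the 36386 genes with reads. One edgeR quasi-likelihood model (glmQLFit and glmQLFTest, robust, TMM factors, R 4.3.3) was fitted over all 8 libraries with group alone as a term, so that the groups shared an estimate of the spread (5 residual degrees of freedom, median prior 4.87, common biological coefficient of variation 0.528). The 3 comparisons were tested two-sided with Benjamini-Hochberg adjustment at 0.05, and a gene is said to have risen or fallen only when it passed. Standard errors of log2 fold changes were derived from the F statistics. Levels are CPM (edgeR's depth-scaled counts, with TMM factors), given as mean ± SD over replicates.

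Gene lists (38, covering 848 distinct genes of which 4 had no symbol match) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the inter-gene correlation preset at 0.01, adjusted over the lists with at least 5 tested members. Camera asks whether a list's genes shift relative to all others. It was repeated with a correlation estimated for each list, under which no list was called in any of the 3 comparisons, and with fry, which asks whether a list's genes move one way on balance. Member counts are given over all genes tested and adjusted over the list alone. The groups, designs, lists, alternatives and the rule for named genes were fixed before the data were examined. For each comparison the rule took the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries, the 4 members with the smallest adjusted p of each list with a called member, and a fixed panel. Genes of the sex chromosomes that tell sex were left out of the named genes.

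The procedure was tested on simulated counts with known changes. For 3D against 2D it recovered 0% of genes changed 2-fold, 20.9% of those changed 4-fold and 71.2% of those changed 8-fold (18738 genes tested). For 3D against day 0 the shares were 2.99%, 26.9% and 60.6% (18737 genes), and for 2D against day 0 they were 1.49%, 17.9% and 54.5% (18815 genes). False calls were 6 of 67, 2 of 62 and 3 of 52 in the same order. In each of the 3 comparisons a simulated list of 30 genes shifted by 1 on the log2 scale was called and 0 of 9 unshifted lists were. The simulated genes varied independently of each other, whereas estimated correlations within the real lists reached 0.986 (ribosomal proteins). False list calls among genes that vary together were therefore not tested by the simulation. Changes of 4-fold or less were thus mostly out of reach for single genes, and many 8-fold changes were missed too.

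Alternatives were DESeq2 size factors, upper-quartile factors, no filter, a filter of 10 reads in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a fit of only the 2 groups compared, the replicate number as a block, the style of the library name as a covariate, mitochondrially encoded genes left out, a test against a fold of 1.5, and each library left out in turn. Leaving out both libraries that stood apart (day 0 replicate 1 and 3D replicate 2) was added after the data were seen. So was keeping only the 5 libraries whose library name does not open with a number standing alone, called words-first below.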

Results

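Transcripts were counted in cardiomyocytes mixed 9:1 with fibroblasts, both derived from the hiPSC line WTC11, before and after 30 days of maturation in either of 2 culture formats. Day 0 and the day 30 3D tissues had 3 libraries each, and the day 30 2D culture had 2. Total counts were 33375267, 29776385 and 28548801 for day 0 replicates 1 to 3. They were 29650902 and 42064789 for 2D replicates 1 and 2, and 25005264, 21864393 and 34751006 for 3D replicates 1 to 3. Between 23673 and 27057 genes had reads per library. The first principal component held 29.9% of the variance and the second 23.1%. Replicates differed widely, and 2 libraries stood apart. Day 0 replicate 1 had a mean log2 CPM of 4.88 over mature sarcomere genes, against 7.62 and 7.24 in the other day 0 libraries. In 3D replicate 2, mitochondrially encoded genes took 21.6% of counts and the 10 most abundant genes 21.8%, against 7.57% to 17.0% and 10.7% to 15.5% in the other 7 libraries.

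The comparison of 3D tissues with 2D culture at day 30 asked what the scaffold format changed at equal age. As lists, extracellular matrix and fibroblast genes were lower in the 3D tissues by camera with a preset correlation, with 6 of 38 and 5 of 23 members called. With an estimated correlation neither list passed (adjusted p = 0.660 for both). Fibronectin (FN1) averaged 692 ± 582 CPM in 3D (SD, n = 3) and 11330 ± 2361 CPM in 2D (n = 2), and the mesenchymal cadherin CDH11 averaged 50.8 ± 24.2 and 642 ± 107 CPM. Genes of the mature sarcomere, of oxidative phosphorylation, of fatty acid use and of glycolysis stood higher in 3D as lists, mostly without single genes passing. None of these lists passed with an estimated correlation either (adjusted p = 0.660 for each). In all, 145 genes differed, with 18 higher and 127 lower in 3D (edgeR, adjusted p under 0.05).

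Among 38 tested fibrillar collagens and matrix proteins, 6 fell, 0 rose and 32 were not called. The list's own adjustment gave 13 falls. Its median log2 fold change was -1.86 (camera, adjusted p = 1.30e-08, and adjusted p = 0.660 with an estimated correlation). EFEMP1, a fibulin-family matrix glycoprotein, had a log2 fold change of -4.57 ± 0.55 (SE, adjusted p = 0.0122). For COL8A1, a short-chain collagen of vessel walls, it was -5.23 ± 0.87 (adjusted p = 0.0346), for the fibulin FBLN2 -4.43 ± 0.70 (adjusted p = 0.0278), and for FN1 -4.03 ± 0.76 (adjusted p = 0.0498). The FN1 call was lost in 14 of 21 alternative settings, among them DESeq2 size factors and upper-quartile factors. Those of EFEMP1, FBLN2 and COL8A1 were lost in 4, 6 and 7 of them. COL1A1, the main chain of type I collagen, averaged 2047 ± 1932 CPM in 3D and 9403 ± 4829 CPM in 2D. Its log2 fold change of -2.20 ± 0.81 did not pass (adjusted p = 0.228). The mean log2 CPM of the list was 8.36 and 7.52 in the 2D libraries and 7.15, 6.02 and 5.09 in 3D replicates 1 to 3, so 3D replicate 3 was the lowest.

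Basement membrane and adhesion genes fell in 3 of 35 cases, with 0 rises, 32 not called and a median of -0.95. Within the list alone 12 fell and 1 rose (camera, adjusted p = 1.80e-05, and adjusted p = 0.660 with an estimated correlation). Those 3 were the laminin chains LAMA1 (-3.59 ± 0.44, adjusted p = 0.0122) and LAMB1 (-2.55 ± 0.41, adjusted p = 0.0286), and ITGA1 (-3.79 ± 0.63, adjusted p = 0.0339), which encodes a collagen-binding integrin subunit. Of 23 fibroblast markers 5 fell, 0 rose and 18 were not called, and 6 fell when adjusted over the list alone. The fibroblast list had a median of -1.47 (camera, adjusted p = 6.81e-04, and adjusted p = 0.660 with an estimated correlation). Those that fell included CDH11 (-3.66 ± 0.47, adjusted p = 0.0135), the microfibril protein MFAP5 (-5.39 ± 0.74, adjusted p = 0.0186), and the collagen receptor DDR2 (-3.37 ± 0.58, adjusted p = 0.0370). The other 2 were the secreted matrix protein CCDC80 (-3.76 ± 0.65, adjusted p = 0.0375) and the surface protein THY1 (-2.99 ± 0.57, adjusted p = 0.0498). The calls of CDH11, MFAP5, DDR2 and CCDC80 were lost in 5, 5, 10 and 11 of 21 alternative settings. For CCDC80 these included the replicate numbers as a block. THY1 was named after its values were seen. Not all fibroblast markers were lower. The actin-severing protein GSN stood at 565 ± 122 CPM in 3D and 254 ± 16.3 CPM in 2D (adjusted p = 0.254). It too was named after its values were seen.

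Among 24 myofibroblast and contractile genes 1 fell, the integrin subunit ITGA11 (-4.13 ± 0.62, adjusted p = 0.0251), and 23 were not called. With adjustment within the list 7 fell and 1 rose. Its median was -0.34 (camera, adjusted p = 0.0244, and adjusted p = 0.660 with an estimated correlation). The call was lost without 3D replicate 3 (adjusted p = 0.319) and with replicate numbers as a block (adjusted p = 0.156). ACTA2, which encodes smooth muscle actin, averaged 836 ± 501 CPM in 3D and 3582 ± 1844 CPM in 2D without passing (adjusted p = 0.195). The 32 matrix remodelling enzymes had 1 rise, PCOLCE, an enhancer of procollagen processing (2.78 ± 0.50, adjusted p = 0.0433), 0 falls and 31 not called. That list's median was -0.73, with 4 higher and 5 lower when adjusted over the list alone (camera, adjusted p = 0.0373, and adjusted p = 0.660 with an estimated correlation). Its call was lost without 2D replicate 1 (adjusted p = 0.0876), 3D replicate 2 (adjusted p = 0.0569) or 3D replicate 3 (adjusted p = 0.257), and with the replicate block (adjusted p = 0.162).

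**Figure D1:**
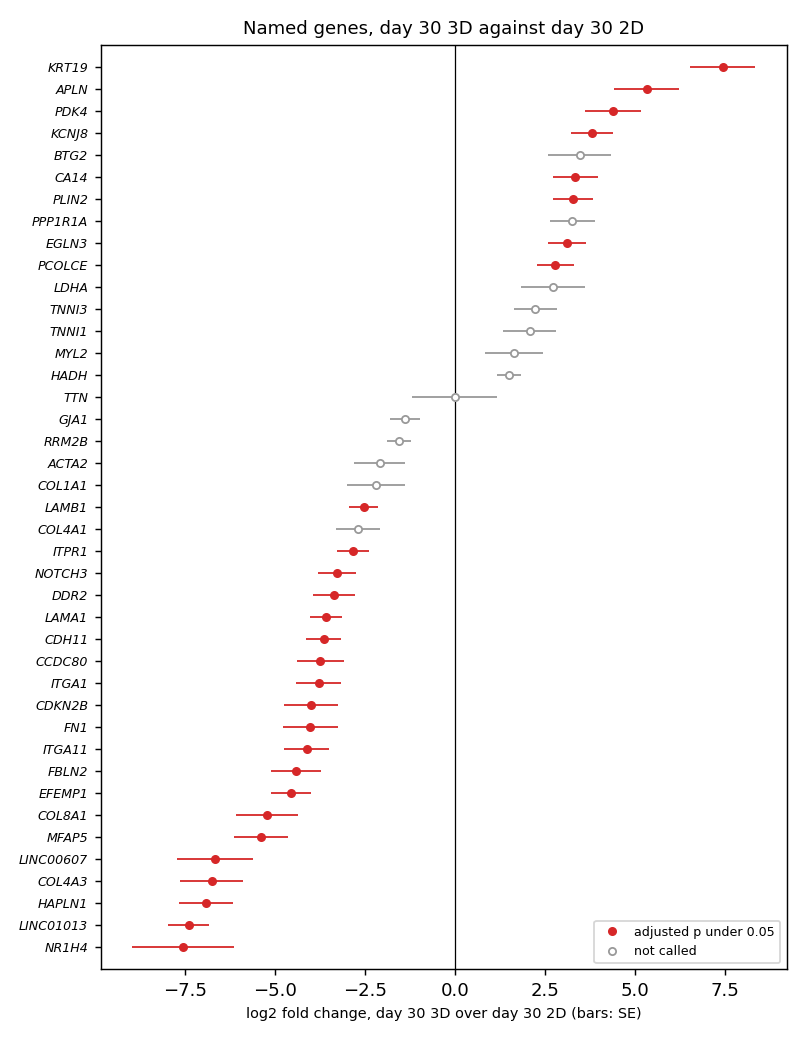
Log2 fold changes of named genes in day 30 3D tissues (n = 3) against day 30 2D culture (n = 2), with bars of 1 SE from the edgeR fit, in order of size, where filled points had an adjusted p under 0.05. Matrix, basement membrane and fibroblast genes such as EFEMP1 (-4.57), LAMA1 (-3.59) and CDH11 (-3.66) lie below 0, and PDK4 (4.38) and PLIN2 (3.27) lie above 0.

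Of 30 mature or ventricular sarcomere genes, 27 had a positive log2 fold change in 3D against 2D, with a median of 1.82. None of the 30 was called over all genes, and 6 rose when adjusted over the list alone (camera, adjusted p = 8.27e-08, and adjusted p = 0.660 with an estimated correlation). Cardiac troponin I (TNNI3) averaged 265 ± 83.6 CPM in 3D and 56.7 ± 32.8 CPM in 2D (2.23 ± 0.60, adjusted p = 0.127). The ventricular myosin light chain MYL2 averaged 1506 ± 643 and 485 ± 120 CPM (1.63 ± 0.81, adjusted p = 0.353). Slow skeletal troponin I (TNNI1), the fetal form in the heart, was at 4458 ± 1328 and 1064 ± 507 CPM (adjusted p = 0.217). Titin (TTN) had a log2 fold change of -0.01 ± 1.18. In the calcium handling list 1 of 26 genes fell, ITPR1, an intracellular calcium release channel (-2.83 ± 0.44, adjusted p = 0.0278), and 25 were not called. In adjustment over that list alone 1 rose and 2 fell. The list was not called (median 0.63, camera, adjusted p = 0.0685) but passed without day 0 replicate 1 (adjusted p = 0.0394) or 2D replicate 2 (adjusted p = 0.00944). Of 30 cardiac ion channel and gap junction genes 1 rose, KCNJ8, a subunit of an ATP-sensitive potassium channel, from 1.23 ± 0.540 to 17.2 ± 6.99 CPM (adjusted p = 0.0267). The other 29 were not called, nor was the list (camera, adjusted p = 0.794). Within the channel list alone 3 rose and 2 fell. The gap junction protein GJA1 was at 191 ± 56.1 CPM in 3D and 502 ± 166 CPM in 2D (adjusted p = 0.153).

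Nuclear-encoded oxidative phosphorylation genes had positive log2 fold changes in 42 of 43 cases (median 0.98), and 0 were called, also when adjusted over the list alone. The shift of the list passed (camera, adjusted p = 2.51e-11, and adjusted p = 0.660 with an estimated correlation). The mitochondrially encoded list was not called (adjusted p = 0.929), and it passed as lower in 3D without 2D replicate 1 (adjusted p = 0.0413). Ribosomal protein genes had a median of 0.52 with 34 of 34 positive and 0 called (camera, adjusted p = 0.0123, and adjusted p = 0.825 with an estimated correlation). That call was lost without 2D replicate 2 (adjusted p = 0.328) or 3D replicate 2 (adjusted p = 0.180). Of 37 genes of fatty acid uptake and oxidation 2 rose, 0 fell and 35 were not called, and 4 rose when adjusted over the list alone. The fatty acid list had a median of 0.91 (camera, adjusted p = 1.41e-07, and adjusted p = 0.660 with an estimated correlation). Those that rose were PDK4, a kinase that restrains pyruvate oxidation (24.4 ± 3.96 CPM in 3D and 1.16 ± 0.574 CPM in 2D, adjusted p = 0.0390), and the lipid droplet protein PLIN2 (46.6 ± 21.8 and 4.84 ± 1.32 CPM, adjusted p = 0.0354). The fatty acid oxidation enzyme HADH was at 95.3 ± 10.5 and 34.1 ± 6.67 CPM (adjusted p = 0.0829). Glycolysis genes were positive in 25 of 26 cases with a median of 1.90. Of these 11 rose when adjusted over the list alone but 0 over all genes (camera, adjusted p = 6.18e-08, and adjusted p = 0.660 with an estimated correlation). Their mean log2 CPM was 9.01 in 3D replicate 3, 7.26 and 7.71 in the other 3D libraries, and 6.34 and 6.66 in 2D. Lactate dehydrogenase A (LDHA) averaged 1690 ± 1223 CPM in 3D and 258 ± 54.2 CPM in 2D (adjusted p = 0.187). Among 26 hypoxia response genes 1 rose, the oxygen-sensing prolyl hydroxylase EGLN3 (3.10 ± 0.54, adjusted p = 0.0370), and 25 were not called. The same number, 1, rose within the list alone. The hypoxia list's median was 1.31 (camera, adjusted p = 0.00308, and adjusted p = 0.660 with an estimated correlation). Its call was lost without 3D replicate 3 (adjusted p = 0.149).

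KRT19, a keratin of epithelia and epicardium, had the largest rise, from 0.789 ± 0.670 CPM in 2D to 139 ± 45.2 CPM in 3D (7.43 ± 0.91, adjusted p = 0.0122). It was the only 1 of 15 epicardial markers called, and that list was not (camera, adjusted p = 0.933). Within the epicardial list alone 1 rose and 1 fell. Against day 0 all 15 epicardial markers, KRT19 included, had negative log2 fold changes in 3D, so KRT19 rose relative to 2D only. The largest falls against 2D included the long noncoding RNA LINC01013 (-7.40 ± 0.57, adjusted p = 0.00310), HAPLN1, which links hyaluronan to proteoglycans (-6.92 ± 0.74, adjusted p = 0.00843), and NR1H4, the bile acid receptor (-7.57 ± 1.41, adjusted p = 0.0473). NR1H4 varied widely in 2D (64.8 ± 55.3 CPM, n = 2). LINC00607 (-6.68 ± 1.07, adjusted p = 0.0295) and COL4A3, a type IV collagen chain (-6.77 ± 0.87, adjusted p = 0.0135), also fell. The peptide ligand APLN (5.31 ± 0.91, adjusted p = 0.0364) and the membrane carbonic anhydrase CA14 (3.33 ± 0.62, adjusted p = 0.0476) rose. Their calls were lost in 10 (APLN) and 16 (CA14) of 21 alternative settings. For CA14 these included the replicate block and the name style as a covariate. Other calls of 3D against 2D were lost in 13 (NR1H4), 12 (EGLN3, PCOLCE), 10 (PDK4) and 9 (PLIN2, LINC00607, LAMB1, ITGA1) settings. Further ones were lost in 8 (KCNJ8, NOTCH3, ITPR1), 7 (ITGA11), 4 (LAMA1, COL4A3), 2 (KRT19), 1 (HAPLN1) and 0 (LINC01013). Of 15 smooth muscle and pericyte markers KCNJ8 rose and NOTCH3, a receptor of mural cells, fell (-3.28 ± 0.53, adjusted p = 0.0299), while 13 were not called, nor was the list (camera, adjusted p = 0.933). With adjustment over the list alone 1 rose and 1 fell. On GRCh38, KRT19 (ENSG00000171345) lies on chromosome 17 from 41523617 to 41528308 and LINC01013 on chromosome 6 from 132131915 to 132169374. HAPLN1 lies on chromosome 5 from 83637805 to 83721613 and EFEMP1 on chromosome 2 from 55865967 to 55924139. LINC00607 lies on chromosome 2 from 215611563 to 215843722, beyond FN1 at 215360440 to 215436172 and on the same strand.

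The count of 145 genes was 7 without 2D replicate 1, 42 without 2D replicate 2, 3 without 3D replicate 2, 18 without 3D replicate 3, 52 without day 0 replicate 2, 12 without both libraries that stood apart, and 41 in the 5 libraries whose name puts words first. It was 177 without day 0 replicate 1, 101 without day 0 replicate 3 and 113 without 3D replicate 1. The number of single-gene calls thus changed with the library left out, also with day 0 replicate 2, which is in neither group compared. Leaving out a library also leaves fewer samples to estimate the shared spread. Whether single libraries carried the differences or the test lost power was not separated. The lowest count, 3, came with both 2D libraries kept.

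**Figure D2:**
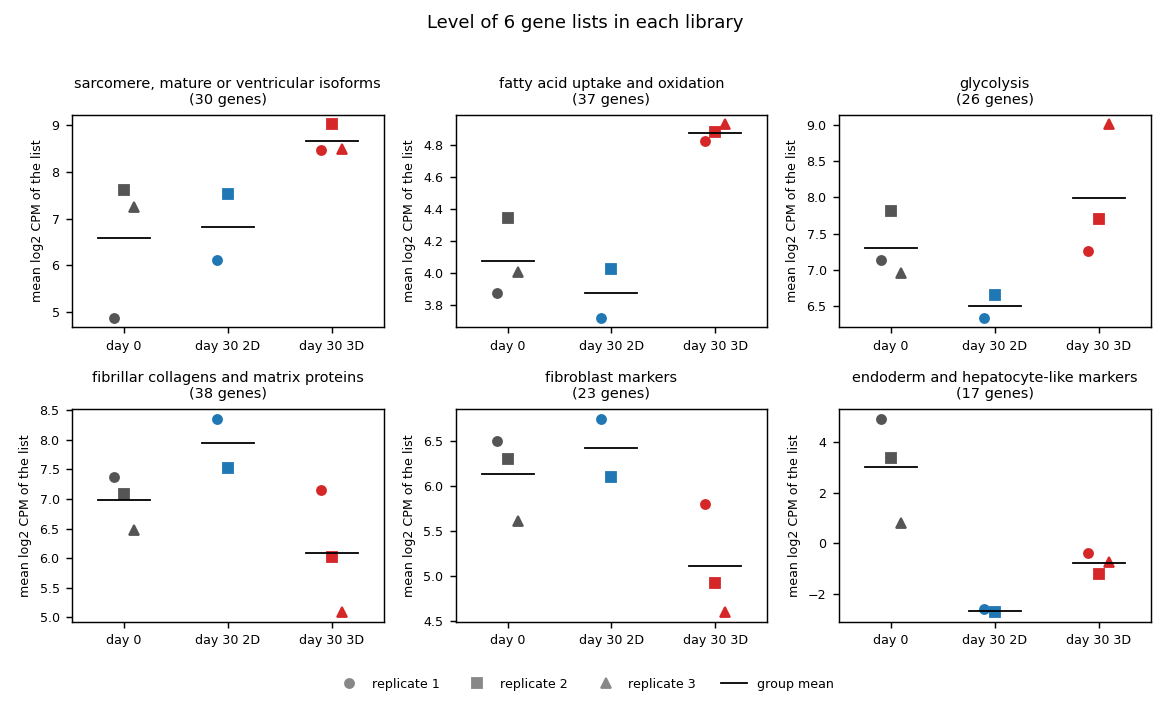
Mean log2 CPM of 6 gene lists in each library (points) by group, with the group mean as a bar. Mature sarcomere genes lie at 8.47, 9.02 and 8.49 in the 3D libraries and at 4.88 in day 0 replicate 1, and endoderm and hepatocyte-like markers fall from 4.93, 3.36 and 0.80 at day 0 to -2.59 and -2.71 in 2D.

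The comparison of 3D tissues with day 0 asked what changed over 30 days of maturation in the scaffold. Mature sarcomere genes were higher in 3D as a list, and markers of pluripotency, epicardium, endoderm and fibroblasts were lower. With an estimated correlation all 5 lists failed to pass (adjusted p from 0.333 to 0.505). With the preset correlation 19 lists were called, but other splits of the 3D and day 0 libraries also gave 10 to 23 called lists. The myosin light chain MYL2 averaged 1506 ± 643 CPM in 3D and 480 ± 352 CPM at day 0 (SD, n = 3 each), and the laminin chain LAMA1, at 62.0 ± 29.6 CPM at day 0, had a log2 fold change of -4.51 ± 0.44 (SE). In all, 24 genes differed, with 3 higher and 21 lower in 3D (edgeR, adjusted p under 0.05).

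Of 30 mature sarcomere genes 29 were positive with a median log2 fold change of 1.72. Over all genes 0 were called, and 6 rose when adjusted over the list alone (camera, adjusted p = 3.29e-11, and adjusted p = 0.466 with an estimated correlation). TNNI3 was at 265 ± 83.6 CPM in 3D and 80.1 ± 41.9 CPM at day 0 (adjusted p = 0.143). The atrial and developing heart myosin MYH6 was at 1295 ± 763 and 578 ± 331 CPM (adjusted p = 0.391), and TNNI1 at 4458 ± 1328 and 1445 ± 961 CPM (adjusted p = 0.235). Calcium handling genes were positive in 20 of 26 cases, 0 called, and adjusted over the list alone 4 rose and 2 fell. The calcium list had a median of 0.68 (camera, adjusted p = 0.00292, and adjusted p = 0.583 with an estimated correlation). The ryanodine receptor RYR2 averaged 418 ± 115 CPM in 3D and 135 ± 118 CPM at day 0 (adjusted p = 0.292). Intercalated disc genes were positive in 19 of 22 cases, 0 called, and adjusted over the list alone 3 rose and 2 fell. The disc list had a median of 0.67 (camera, adjusted p = 0.00362, and adjusted p = 0.616 with an estimated correlation). Day 0 replicate 1 was low in sarcomere genes. Without it the calcium handling (adjusted p = 0.0993) and intercalated disc (adjusted p = 0.110) calls were lost, and the sarcomere call held (adjusted p = 1.78e-07). In the 5 libraries whose name puts words first, the calcium handling list had adjusted p = 0.120 and the intercalated disc list adjusted p = 0.0552.

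Fatty acid genes were positive in 34 of 37 cases, 0 called, and adjusted over the list alone 8 rose and 1 fell. Their median was 0.64 (camera, adjusted p = 1.65e-06, and adjusted p = 0.333 with an estimated correlation). The fatty acid carrier FABP3 averaged 1068 ± 457 CPM in 3D and 323 ± 214 CPM at day 0 (adjusted p = 0.245). Oxidative phosphorylation genes were positive in 40 of 43 cases (median 0.49, 0 called, camera, adjusted p = 1.59e-05, and adjusted p = 0.616 with an estimated correlation). The mitochondrially encoded list was not called (adjusted p = 0.111), and it passed as lower in 3D without 3D replicate 2 (adjusted p = 0.00188) and without both libraries that stood apart (adjusted p = 0.00487). The ribosomal protein list was not called either (adjusted p = 0.942), and it passed as higher in 3D without day 0 replicate 1 (adjusted p = 2.27e-04) and as lower without day 0 replicate 3 (adjusted p = 1.12e-04). It also passed as higher without both libraries that stood apart (adjusted p = 0.0408) and in the words-first libraries (adjusted p = 0.00466). Adrenergic and cAMP signalling genes were positive in 14 of 17 cases (median 0.77, 0 called, camera, adjusted p = 6.42e-04, and adjusted p = 0.333 with an estimated correlation). Glycolysis genes were positive in 24 of 26 cases (median 0.67, 0 called, camera, adjusted p = 0.00445, and adjusted p = 0.646 with an estimated correlation). That call was lost without 3D replicate 3 (adjusted p = 0.663) or day 0 replicate 3 (adjusted p = 0.0832). For oxidative phosphorylation, adrenergic and glycolysis genes 0 members were called when adjusted over the list alone.

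Of 12 pluripotency markers in the list only 6 were tested. Of these 1 fell, LIN28B, an RNA-binding protein that blocks let-7 maturation (-3.28 ± 0.49, adjusted p = 0.0471), and 5 were not called. The LIN28B call was lost in 14 of 21 alternative settings, among them leaving out any single library. Adjusted over the list alone 4 fell (median -2.99, camera, adjusted p = 4.41e-06, and adjusted p = 0.333 with an estimated correlation). Its paralog LIN28A was at 0.220 ± 0.180 CPM in 3D and 8.88 ± 6.80 CPM at day 0 (adjusted p = 0.0706). Of 15 epicardial markers 1 fell, the zinc finger protein BNC1 (-7.13 ± 0.74, adjusted p = 0.00860), and 14 were not called. Within their list alone 6 epicardial markers fell (median -2.01, camera, adjusted p = 1.59e-05, and adjusted p = 0.333 with an estimated correlation). TCF21, a transcription factor of epicardium and fibroblasts that is in the fibroblast list and not the epicardial list, was at 1.04 ± 0.586 and 25.1 ± 23.8 CPM (adjusted p = 0.0614). The surface sialomucin PODXL was at 6.31 ± 3.67 and 144 ± 173 CPM (adjusted p = 0.0785), and the keratin KRT7 at 0.371 ± 0.235 and 6.35 ± 2.84 CPM (adjusted p = 0.0758). Endoderm and hepatocyte-like markers were negative in 17 of 17 cases with a median of -4.51. Over all genes 0 of them were called, and 14 fell when adjusted over the list alone (camera, adjusted p = 3.54e-11, and adjusted p = 0.333 with an estimated correlation). Their mean log2 CPM was 4.93, 3.36 and 0.80 in day 0 replicates 1 to 3 and -0.37, -1.22 and -0.73 in 3D. Epicardial markers had a mean log2 CPM of 6.46 in day 0 replicate 1 and of 4.16 and 3.78 in the other day 0 libraries.

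Fibroblast markers fell in 1 of 23 cases, MFAP5 (-4.81 ± 0.71, adjusted p = 0.0462), with 22 not called. Adjusted over the list alone, 8 fibroblast markers fell and 1 rose (median -0.89, camera, adjusted p = 4.12e-04, and adjusted p = 0.505 with an estimated correlation). CDH11 was at 50.8 ± 24.2 CPM in 3D and 273 ± 68.3 CPM at day 0 (adjusted p = 0.0614). Matrix proteins fell in 1 of 38 cases, again MFAP5, with 37 not called. Within the matrix list alone 8 fell and 1 rose (median -0.77, camera, adjusted p = 2.18e-04, and adjusted p = 0.616 with an estimated correlation). FN1 was at 692 ± 582 and 4072 ± 508 CPM (adjusted p = 0.124). The collagen chain COL11A1 was at 10.9 ± 4.11 and 92.9 ± 64.1 CPM (adjusted p = 0.0614) and COL3A1 at 2336 ± 1903 and 5774 ± 2899 CPM (adjusted p = 0.432). Without 3D replicate 3 the matrix protein call was lost (adjusted p = 0.0567), and in the 5 libraries whose name puts words first it had adjusted p = 0.284. Basement membrane genes fell in 1 of 35 cases, LAMA1 (-4.51 ± 0.44, adjusted p = 0.00860), with 34 not called. Within their list alone 5 basement membrane genes fell (median -0.44, camera, adjusted p = 0.0386, and adjusted p = 0.665 with an estimated correlation). That call was lost without day 0 replicate 3 (adjusted p = 0.366) or 3D replicate 3 (adjusted p = 0.250), and with the replicate block (adjusted p = 0.0680). Matrix remodelling enzymes were negative in 22 of 32 cases with 0 called on either count (median -0.85, camera, adjusted p = 5.32e-04, and adjusted p = 0.333 with an estimated correlation).

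The 3 genes that rose were CPNE5, a copine that binds phospholipids with calcium, from 7.38 ± 3.70 to 192 ± 47.3 CPM (4.70 ± 0.45, adjusted p = 0.00860), and the calcium-binding protein CALN1 (4.77 ± 0.59, adjusted p = 0.0272) and the membrane protein TMEM200C (2.90 ± 0.41, adjusted p = 0.0454). Besides BNC1, the largest falls were the copine CPNE7 (-5.64 ± 0.72, adjusted p = 0.0300), HAPLN1 (-5.41 ± 0.68, adjusted p = 0.0276), vitronectin (VTN, -5.23 ± 0.75, adjusted p = 0.0454) and the ubiquitin ligase MARCHF4 (-5.17 ± 0.54, adjusted p = 0.00860). Of 21 alternative settings, the call was lost in 12 for TMEM200C, VTN and MFAP5, 10 for CPNE7, 9 for CALN1 and 7 for HAPLN1. It was lost in 5 for MARCHF4, 4 for BNC1, 3 for LAMA1 and 2 for CPNE5. HAPLN1 was the only 1 of 12 chondrocyte and osteoblast markers called. Within that list alone 4 of them fell (median -1.49, camera, adjusted p = 0.00362, and adjusted p = 0.333 with an estimated correlation). That list's call was lost without 3D replicate 3 (adjusted p = 0.0924). On GRCh38, CPNE5 lies on chromosome 6 from 36740775 to 36840002 and LAMA1 on chromosome 18 from 6941744 to 7117814. BNC1 lies on chromosome 15 from 83255903 to 83284714 and MARCHF4 on chromosome 2 from 216257865 to 216372027. The count of 24 genes was 12, 7 and 49 without day 0 replicates 1, 2 and 3, 6 and 7 without 2D replicates 1 and 2, and 10, 0 and 2 without 3D replicates 1, 2 and 3. It was 5 without both libraries that stood apart and 47 in the 5 libraries whose name puts words first.

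The comparison of 2D culture with day 0 asked what changed over 30 days of conventional culture. No single gene passed: 0 genes were called by edgeR, with a smallest adjusted p of 0.135. An unadjusted p under 0.05 was found for 1755 genes (968 by chance), and the DESeq2 Wald test called 534 and limma-voom 0. As lists, cell cycle, pluripotency, epicardial and endoderm-like genes were lower in 2D and matrix proteins higher. With an estimated correlation none of them passed (adjusted p from 0.183 to 0.785). FN1 averaged 11330 ± 2361 CPM in 2D (SD, n = 2) and 4072 ± 508 CPM at day 0 (n = 3), a log2 fold change of 1.48 ± 0.72 (adjusted p = 0.576).

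Of 40 cell cycle genes 40 were negative with a median of -1.44. Adjusted over the list alone 12 fell (camera, adjusted p = 2.23e-15, and adjusted p = 0.535 with an estimated correlation). The proliferation marker MKI67 was at 28.5 ± 15.2 CPM in 2D and 77.6 ± 76.6 CPM at day 0 (adjusted p = 0.644). Its log2 fold change of -1.45 ranged from -2.13 to -0.24 over the settings, the last without day 0 replicate 3. The topoisomerase TOP2A was at 50.1 ± 10.4 and 108 ± 30.4 CPM (adjusted p = 0.606). Pluripotency markers were negative in 6 of 6 cases, with 4 falls adjusted over the list alone (median -3.43, camera, adjusted p = 1.01e-08, and adjusted p = 0.183 with an estimated correlation). Epicardial markers were negative in 14 of 15 cases, with 7 falls adjusted over the list alone (median -2.48, camera, adjusted p = 2.08e-07, and adjusted p = 0.493 with an estimated correlation). Endoderm and hepatocyte-like markers were negative in 17 of 17 cases, with 15 falls adjusted over the list alone (camera, adjusted p = 1.79e-21, and adjusted p = 0.361 with an estimated correlation). In 2D 5 of these 17 had no read, and with those set to the floor of 3 counts over the group the median was -6.86.

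Matrix proteins were positive in 28 of 38 cases, with 2 rises adjusted over the list alone (median 1.02, camera, adjusted p = 5.47e-04, and adjusted p = 0.785 with an estimated correlation). COL1A1 was at 9403 ± 4829 CPM in 2D and 2896 ± 781 CPM at day 0 (adjusted p = 0.566), and ACTA2 at 3582 ± 1844 and 1022 ± 395 CPM (adjusted p = 0.486). The fibroblast marker list was not called (median 0.52, adjusted p = 0.445). Basement membrane genes were positive in 27 of 35 cases with 0 called on either count (median 0.46, camera, adjusted p = 0.00189, and adjusted p = 0.785 with an estimated correlation), and the call was lost without day 0 replicate 1 (adjusted p = 0.0866) or 2D replicate 2 (adjusted p = 0.0655).

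Mature sarcomere genes were not called in 2D against day 0 (adjusted p = 0.613), with a median of -0.25 although camera's direction was up. They passed as lower in 2D without day 0 replicate 1 (adjusted p = 0.00176) or without both libraries that stood apart (adjusted p = 0.00555), and as higher in 2D without day 0 replicate 2 (adjusted p = 0.0358) or 2D replicate 1 (adjusted p = 0.00179), so single libraries set the direction. MYL2 was at 485 ± 120 CPM in 2D and 480 ± 352 CPM at day 0. MYH7, the main ventricular myosin, was at 3481 ± 2987 and 4310 ± 4594 CPM, and TNNI3 at 56.7 ± 32.8 and 80.1 ± 41.9 CPM, all within about 1 SE of no change. The natriuretic peptides NPPA (1.41 ± 0.72, adjusted p = 0.593) and NPPB (-1.16 ± 0.83, adjusted p = 0.723) were not called. Nor were calsequestrin CASQ2 (1.53 ± 1.19, adjusted p = 0.747) and GJA1 (0.67 ± 0.41, adjusted p = 0.669). Oxidative phosphorylation genes were negative in 40 of 43 cases (median -0.46, camera, adjusted p = 1.16e-04, and adjusted p = 0.785 with an estimated correlation). That call was lost without 2D replicate 1 (adjusted p = 0.142). Glycolysis genes were negative in 23 of 26 cases (median -1.06, camera, adjusted p = 2.42e-04, and adjusted p = 0.785 with an estimated correlation). Ribosomal protein genes had a median of -0.86 (camera, adjusted p = 0.00209, and adjusted p = 0.785 with an estimated correlation). Without day 0 replicate 1, which had their highest mean log2 CPM at 11.2, the direction turned and the call was lost (adjusted p = 0.934). It was also lost without 2D replicate 2 (adjusted p = 0.276). The mitochondrially encoded list was not called (adjusted p = 0.136), and it passed as lower in 2D without 2D replicate 2 (adjusted p = 0.00120) and with the replicate block (adjusted p = 0.00349). Leaving out single libraries gave at most 3 genes, without day 0 replicate 3, and the 5 libraries whose name puts words first gave 1.

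**Figure D3:**
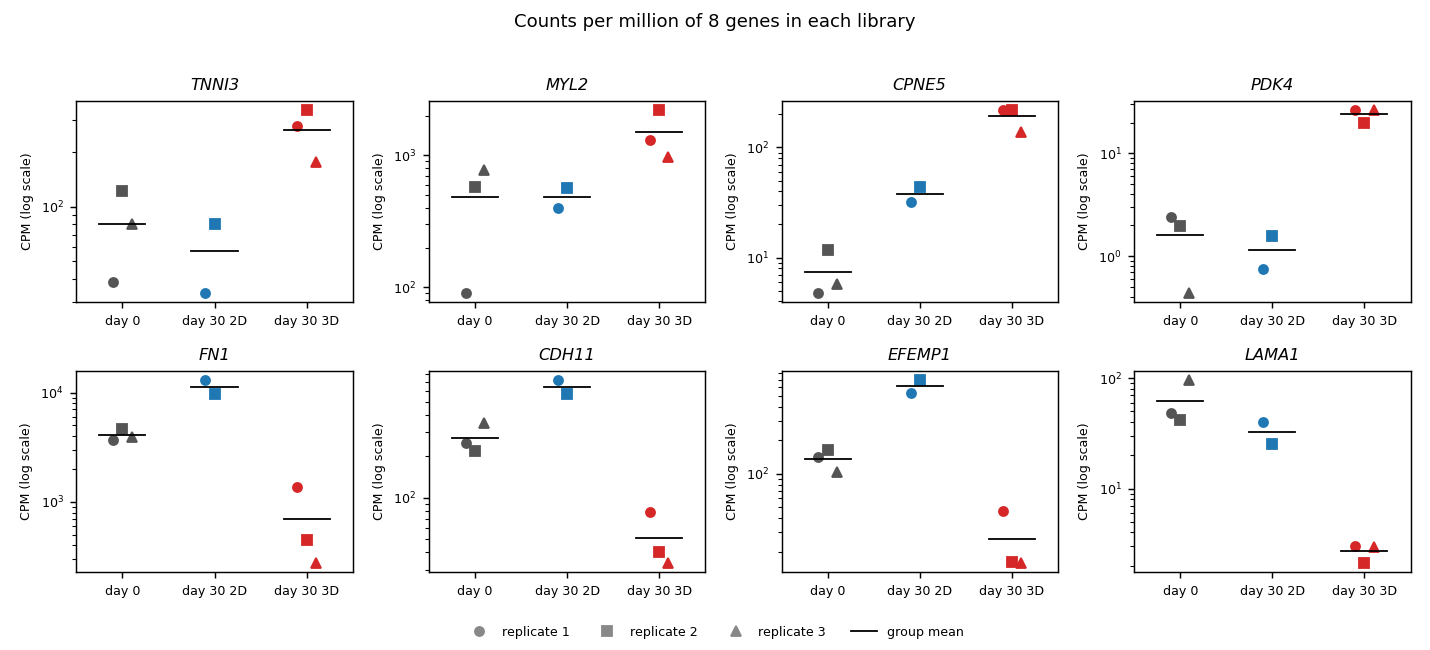
CPM of named genes in each library (points, log axis) with the group mean as a bar, for day 0 (n = 3), day 30 2D (n = 2) and day 30 3D (n = 3). FN1 averaged 4072, 11330 and 692 CPM in that order, and MYL2 480, 485 and 1506 CPM.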

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

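Leaving out both libraries that stood apart and keeping the words-first libraries were chosen after the data were seen. Counts below are in the order 2D against day 0, 3D against day 0 and 3D against 2D, where all libraries and the stated model gave 0, 24 and 145 genes. No called gene changed sign in any alternative. DESeq2 size factors gave 0, 24 and 137, a filter of 10 reads in 2 libraries 0, 24 and 145, and leaving out mitochondrially encoded genes 0, 22 and 125. Without a filter the counts were 846, 1832 and 1680, with all 24 and 145 genes among them. In that fit the prior degrees of freedom were infinite, but the gene set differed too, so the cause is open. The DESeq2 Wald test gave 534, 1402 and 1380, limma-voom 0, 5 and 145, and the test against a fold of 1.5 gave 0, 10 and 85. Upper-quartile factors gave 0, 15 and 111. A fit of only the 2 groups compared gave 0, 5 and 35, with fewer samples to estimate the spread. The name style as a covariate gave 0, 53 and 111, with 52 of the 145 lost in the last. For causes not stated here, the cause was not tested. Leaving out 1 library gave 0 to 3, 0 to 49 and 3 to 177 genes, and where 1 library of 2D remained it was assumed to vary like the other groups. Both libraries out gave 0, 5 and 12, and the words-first libraries 1, 47 and 41. The other name style has 1 library per group and so no test.

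The replicate numbers of the titles as a block gave 0, 174 and 311 genes. Same-numbered libraries correlated in their deviations from group means at 0.0627, 0.149 and 0.121 between day 0 and 3D, at 0.339 and 0.176 between day 0 and 2D, and at 0.0148 and -0.0291 between 2D and 3D, so the numbers were not taken to pair the samples. Day 0 replicate 3 correlated with 2D replicate 2 at 0.201, above the 0.176 of the same-numbered pair. With 2 libraries the 2D deviations mirror each other, and both same-numbered pairs of day 0 and 2D also share a name style. Between day 0 and 3D every library correlated best with its own number. With 3 libraries per group few matchings are possible, so this is a weak hint from the data and not the design.

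Gene lists called by camera were 16, 19 and 15. With an estimated correlation they were 0, 0 and 0. Fry called 1, 1 and 0, pluripotency markers in both cases (adjusted p = 0.0161 and 0.0192). Leaving out 1 library gave 14 to 20, 14 to 24 and 12 to 19. Over the 14 other camera settings, 10 of 16, 9 of 19 and 9 of 15 lists were called throughout. Both libraries out ended 4, 2 and 4 list calls, and the words-first libraries 2, 8 and 4. The replicate block ended 1, 1 and 3 list calls: p53 response in 2D against day 0, basement membrane in 3D against day 0, and myofibroblast, matrix remodelling and p53 response in 3D against 2D. Of the called genes that the naming rule gave and that were followed through all settings, 0 of 11 for 3D against day 0 and 1 of 28 for 3D against 2D (LINC01013) were called in all 21 settings. THY1, named after its values were seen, was not followed. No overlap of calls of 2D and 3D against day 0 could be given, because 2D had 0 calls. Every library held at least 21864393 counts, and the effect of depth on the calls was not tested.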

Other observations

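Of the tests below, the ratio test of endoderm-like markers, the length adjustment of the sarcomere list and both counts over splits of the libraries were set before their results were seen, and the others were chosen after.

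Immediate early genes, which respond within minutes to stimulation or stress, stood higher in 3D than in 2D. Of 25, 21 were positive with a median log2 fold change of 1.45, 0 were called over all genes and 11 rose when adjusted over the list alone (camera, adjusted p = 8.18e-05, and adjusted p = 0.660 with an estimated correlation). Against day 0 they were lower in 2D (median -1.32, camera, adjusted p = 3.90e-04, and adjusted p = 0.785 with an estimated correlation). Their mean log2 CPM was 5.75, 6.40 and 5.03 in the 3D libraries, 4.52 and 3.89 in 2D, and 5.97, 6.10 and 3.82 at day 0. Cell cycle genes were positive in 35 of 40 cases in 3D against 2D with 0 called (median 0.77, camera, adjusted p = 2.54e-04, and adjusted p = 0.660 with an estimated correlation), and that call was lost without 3D replicate 2 (adjusted p = 0.0606). Against day 0 they were negative in 33 of 40 cases in 3D (median -0.50, camera, adjusted p = 6.42e-04, and adjusted p = 0.646 with an estimated correlation), a call lost without 3D replicate 1 (adjusted p = 0.173). Among 22 p53 response and apoptosis genes 1 fell in 3D against 2D, the cell cycle inhibitor CDKN2B (-4.00 ± 0.74, adjusted p = 0.0467). The CDKN2B call was lost in 13 of 21 settings, and its count is uncertain because genes on the other strand cover its span. The ribonucleotide reductase subunit RRM2B was at 28.0 ± 1.82 and 82.5 ± 20.3 CPM (adjusted p = 0.0748). The antiproliferative factor BTG2 was at 449 ± 422 and 40.9 ± 16.6 CPM (adjusted p = 0.115). Within the p53 list alone 1 rose and 5 fell. That list was lower (median -0.50, camera, adjusted p = 0.0244, and adjusted p = 0.660 with an estimated correlation), and the call was lost without 2D replicate 2 (adjusted p = 0.219), 3D replicate 2 (adjusted p = 0.0962) or 3D replicate 3 (adjusted p = 0.137), and with the replicate block (adjusted p = 0.0792).

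Endothelial markers were negative in 16 of 18 cases in 2D against day 0, with 4 falls adjusted over the list alone (median -2.63, camera, adjusted p = 1.46e-07, and adjusted p = 0.535 with an estimated correlation). In 3D against day 0 they were also negative in 16 of 18 (median -1.08, camera, adjusted p = 0.00203, and adjusted p = 0.583 with an estimated correlation), a call lost without 3D replicate 3 (adjusted p = 0.139). Inflammatory cytokines and chemokines were lower in 2D than at day 0 (median -1.97, camera, adjusted p = 9.84e-04, and adjusted p = 0.785 with an estimated correlation), with a mean log2 CPM of 2.91, 3.55 and 1.01 at day 0, 1.09 and 0.65 in 2D, and 3.19, 2.14 and -0.32 in 3D. Endoderm and hepatocyte-like markers, lowest in 2D, were positive in 15 of 17 cases in 3D against 2D, with 4 rises adjusted over the list alone and 5 of them without a read in 2D (camera, adjusted p = 0.00252, and adjusted p = 0.660 with an estimated correlation). Alpha-fetoprotein (AFP), named after its values were seen, stood at 2694, 750 and 16.8 CPM in day 0 replicates 1 to 3, at 1.57 and 0.351 CPM in 2D and at 8.66, 2.17 and 4.50 CPM in 3D.

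Matrix and fibroblast genes were lower in 3D than in 2D. A lower share of fibroblasts would lower markers made only by fibroblasts by about 1 factor. Of the 23 markers, 7 lay over 2 SE above the list's median of -1.47, among them GSN (1.15 ± 0.46) and S100A4 (2.81 ± 0.99). By chance 0.523 would, if the genes varied independently. The rest of the 7 were LUM (1.32 ± 0.68), PDPN (0.75 ± 0.43), TWIST1 (0.47 ± 0.54), DCN (0.59 ± 0.76) and PI16 (1.60 ± 1.52). These genes were named after their values were seen. The 23 markers thus did not all shift by 1 factor. Markers that the cardiomyocytes also express would not fall with the share. Whether the cardiomyocytes express the 7 was not tested, so the test cannot decide whether a lower share was the cause. Of the fibroblast list 7 genes are also matrix genes, and fibroblasts of another state remain possible. Without 3D replicate 3, the lowest library, the matrix list's median was -1.43 (SE 0.38), and after adjustment for transcript length it was -1.66 (SE 0.39), which argues against that library or length as the whole cause. A response of the cells to the scaffold is a candidate explanation that stays open and was not tested here.

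Endoderm and hepatocyte-like transcripts were abundant at day 0 in amounts that differed between libraries. Cells of 1 other lineage would keep genes made only by them in 1 ratio between libraries. The spread of the list's log2 ratios (1.19) lay at percentile 93.4 of 10000 random lists matched on mean expression (median 0.795). Those lists were not matched on differences between libraries, and this list differed by a mean log2 of 4.13 between replicates 1 and 3. Genes with few reads in replicate 3, or also made by the other cells, would not keep 1 ratio. The test thus cannot decide for or against a single such population. The list mixes plasma protein genes of hepatocytes with early endoderm and epithelial genes, and 1 of its 17 genes is in another list. Other cells, of 1 population or more, could still be the source. Without day 0 replicate 1 the median in 3D against day 0 was -3.81 (SE 0.71), so that library was not the sole source. Loss of such cells, or of these transcripts from the same cells, over 30 days stays open as a biological difference and was not tested.

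Mature sarcomere genes stood higher in 3D than at day 0. Without day 0 replicate 1, the library low in these genes, the median was 1.24 (SE 0.24), and after adjustment for transcript length it was 1.64 (SE 0.23), so neither accounts for the whole shift. A higher share of cardiomyocytes would raise transcription factors made only by cardiomyocytes alike. The sarcomere median exceeded that of the cardiomyocyte factors by 1.18 (SE 0.34). All SE of medians in this section are over genes taken as independent, whereas the estimated correlation in the sarcomere list was 0.638. Of the 23 factors, 6 also mark atrial, nodal or other cells, and factors made by other cells would not rise with the share. The test thus cannot decide for or against share. Over the same 30 days in 2D the list was not called (median -0.25, adjusted p = 0.613), and at day 30 it was higher in 3D than in 2D (median 1.82, adjusted p = 8.27e-08, and adjusted p = 0.660 with an estimated correlation). Fetal, atrial or slow-skeletal sarcomere genes were not called in 3D against 2D (10 of 14 positive, median 1.35, camera, adjusted p = 0.200) or against day 0 (median -0.50, adjusted p = 0.326, with camera's direction up), so a fall of fetal forms was not shown. Single libraries set the direction in 2D, and maturation in the scaffold stays open as a candidate explanation. The 3D and day 0 libraries allow 10 splits, too few for a share under 0.05. The real split gave 24 genes (1 of 10 as large) and the highest other 0. It gave 19 lists, where 4 of 10 splits gave as many and the other splits gave 10 to 23. Camera with the preset correlation thus called at least 10 lists in every split, so the number of list calls does not tell the real groups from other splits.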
